A study of Homo sapiens with 6 samples.

How the data were processed

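RNA sequencing was carried out on 6 libraries of K562, an established human cell line from a chronic myeloid leukaemia in blast crisis that carries the BCR-ABL1 fusion and an erythroid and megakaryocytic character. Per the labels, 3 libraries came from cells given a control short hairpin RNA (shRNA) and 3 from cells given an shRNA against STAU2, and stranded Illumina TruSeq libraries were made from total RNA. The labels do not give the hairpin sequences, the number of hairpins, the time after infection or whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

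The authors deposited 1 table of TPM (a transcript abundance scaled to a fixed total per library), with 1 row per gene symbol and 1 column per library. Per the submitters' processing notes, kallisto and sleuth were used with build hg38. Their versions, the transcript index and the way transcripts were summed to genes are not given in the sources used here. The table held 20241 genes, of which 8 had no value in any library. The columns summed to between 874708 and 899875 TPM, because the table holds part of the genes and few noncoding ones. TPM keeps no read count, so the depth is unknown and no counting interval was computed.

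The authors also deposited a table of their own sleuth comparison, with 6446 rows, each with an effect on the natural log scale and its standard error, a p-value and a q-value, and a between-library variance, per the file headers. The largest q-value in the authors' deposited table was 0.0500, so it lists called genes only. Its effects pointed from control shRNA to STAU2 shRNA, by the sign of STAU2 itself. Of the rows of the authors' deposited table, 286 (4.44%) had gene identifiers outside the primary assembly, and 151 symbols had several rows.

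Gene levels were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trended prior) on log2(TPM + 1). Genes with a mean of at least 1 TPM over the 6 libraries were tested (11817 genes), with no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are STAU2 shRNA against control shRNA on the log2(TPM + 1) scale, which understates the change of genes with low levels. The numbers of the replicates did not pair the libraries, and no block was used. Of the tested genes, 11772 matched 1 gene of GENCODE release 29 on GRCh38 (hg38), which gave the coordinates, and 97.8% of these were protein coding.

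Before the data were examined, 29 gene lists were fixed. The 27 lists with at least 5 tested members were tested with camera (limma, preset correlation 0.01, two-sided), with adjustment over the lists. Camera with an estimated correlation and fry were run as alternatives. The rule for named genes was fixed at the same time. It took STAU2, the 10 largest rises and the 10 largest falls among called genes whose group ranges did not overlap and whose mean was at least 5 TPM, and in each list the 2 called members that rose most and the 2 that fell most. KDM1A, MYC, GATA1, HBG1, STAU1 and UPF1 were added whatever their result. Some genes that the rule takes are not reported here. Other genes named in the text were chosen after their values were seen.

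Every 7-base word found in the annotated 3′ UTRs of at least 50 of 11437 tested genes was scored for the fold changes of the genes that hold it, after removal of trends with UTR length, GC content and level. The 3′ UTR of 1 principal protein-coding transcript per gene was used, and fold changes were limited to 1.5 in size. Family-wise p-values came from 1000 permutations of genes. The 4 words scored lowest (CCTAATA, CTAATAA, ACCTAAT and GACCTAA) are called lower-linked words below, and the 2 scored highest (GAAGATC and AAGATCA) higher-linked words. A word in a 3′ UTR is the kind of site a small RNA pairs with through its seed.

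The alternatives were other pseudocounts (0.1 and 5 TPM), other filters (none, and a mean of at least 5 TPM), quantile normalization, scaling by trimmed means of log ratios (TMM, 30% of ratios and 5% of means trimmed, written out for TPM), array weights, no trend, a replicate block, each library left out, an adjusted p under 0.01 and a minimum of 2-fold. The table had 1 row per gene, so a test on unsummed rows was not needed. Tests without genes that hold a word, and without mitochondrial genes, were chosen after seeing the data. Data were simulated for this comparison over the 11817 genes, with independent noise and only 200 genes changed per run. There the limma test recovered 23.6% of genes changed by 0.2 on the log2 scale, 84.4% at 0.5, 99.2% at 1 and 100% at 2. It called 0.0671% of unchanged genes. Far more genes were called in the real data, so these rates do not carry over to the real calls. The word score found the planted word in 20 of 20 simulations. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.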

Results

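Transcript levels were measured in K562 cells with a control shRNA (3 libraries) and with an shRNA against STAU2 (3 libraries). STAU2 encodes Staufen 2, a protein that binds double-stranded RNA and takes part in mRNA transport and decay. The comparison asks which transcripts differ once STAU2 is reduced in cells of blast crisis chronic myeloid leukaemia. Within groups, log2(TPM + 1) correlated across genes at 0.994 to 0.996 (Pearson's r), and between groups at 0.974 to 0.977. Genes are not independent replicates.

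STAU2 itself (ENSG00000040341, chromosome 8, 73420369 to 73747708, minus strand, hg38) was lower in each library labelled STAU2 shRNA. It stood at 27.0, 28.5 and 28.6 TPM in the control libraries and at 12.4, 11.9 and 15.3 TPM in the others. The means were 28.0 ± 0.928 and 13.2 ± 1.81 TPM (SD, n = 3 each), so that 47.1% of the transcript was left. The log2 fold change was -1.04 (SE 0.0877, limma adjusted p = 2.31e-05). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. STAU1 (chromosome 20, 49113339 to 49188367, minus strand), the paralog with related RNA-binding domains, went the other way, from 32.0 ± 0.687 to 59.0 ± 2.5 TPM (log2 fold change 0.86, SE 0.0446). The higher-linked word AAGATCA stands in all 8 annotated STAU1 3′ UTRs and GAAGATC in 3 of them, at separate sites.

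**Figure D1:**
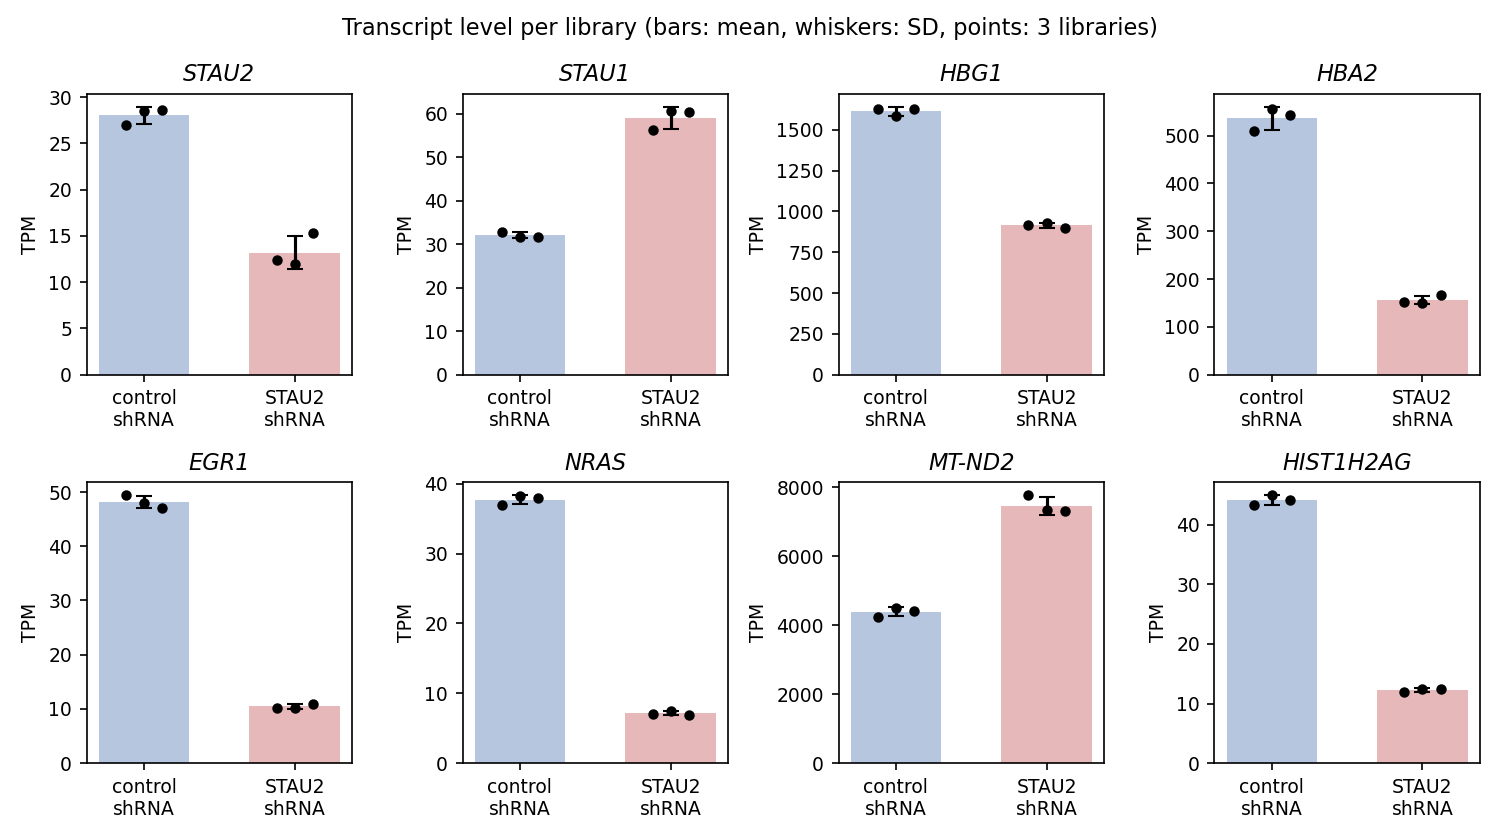
TPM of 8 genes in each library (vertical axis, TPM, starting at 0), with bars for the mean, whiskers for the SD and points for the 3 libraries of each group. STAU2 fell and STAU1 rose, HBG1, HBA2, EGR1, NRAS and the histone gene HIST1H2AG fell, and MT-ND2 rose, with no overlap between the groups in any of the 8.

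The change was broad and mostly small. Of 11817 genes tested, 6081 (51.5%) were called, with 2656 higher and 3425 lower in STAU2 shRNA. The excess of lower calls depended on scaling, with 2998 higher and 3055 lower under quantile normalization, 2963 and 3087 under TMM scaling, and 3228 and 2859 without mitochondrial genes, a setting chosen after seeing the data. At least 2-fold changes were found for 302 genes, 108 higher and 194 lower. These numbers depend on the pseudocount: 185 were higher and 302 lower with 0.1 TPM, and 41 and 64 with 5 TPM. In all, 2332 called genes changed by less than 0.3 on the log2 scale. The groups did not overlap in 7100 genes (60.1%), against 10% by chance. The median log2 fold change of all tested genes was -0.03.

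Among the largest rises, KLHDC7B went from 1.96 ± 1.75 to 39.99 ± 3.14 TPM (SD, n = 3 each, log2 fold change 3.98, SE 0.388). AFP, the fetal serum protein alpha-fetoprotein, rose by a log2 fold change of 2.44, the transcription factor gene MEF2B by 2.33, and ASS1, which makes argininosuccinate in arginine synthesis, by 2.22. CPZ (2.08), CSTA (2.04), COA6 (1.97), FNDC3A (1.90), FAM107B (1.84) and OPN3 (1.83) completed the 10 largest rises. The 3′ UTRs of KLHDC7B, COA6 and FNDC3A hold a higher-linked word, and that of OPN3 holds a lower-linked one. The mean of the control libraries was under 3 TPM for 6 of these 10 genes, so their folds depend on the pseudocount.

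The largest falls were led by VGF and SYP. VGF, a neurosecretory protein gene, fell from 29.6 ± 1.38 to 1.03 ± 0.148 TPM (log2 fold change -3.92, SE 0.0868), and SYP, which encodes the synaptic vesicle protein synaptophysin, from 22.9 ± 1.19 to 1.52 ± 0.0321 TPM (-3.24). TMEM145 (-2.55), CRYBA2 (-2.44), TMEM158 (-2.19), the globin pseudogene HBBP1 (-2.14) and the neuronal tubulin gene TUBB3 (-2.05) also fell. NRAS, a RAS family oncogene (chromosome 1, 114704469 to 114716894, minus strand), fell from 37.7 ± 0.641 to 7.17 ± 0.259 TPM (-2.24), and its 3′ UTR holds all 4 lower-linked words. PIR (-2.14), whose 3′ UTR holds ACCTAAT, and the immediate early gene EGR1 (-2.10, from 48.2 ± 1.14 to 10.5 ± 0.392 TPM) were the others. HBBP1 shares sequence with the globin genes and its value is uncertain.

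**Figure D2:**
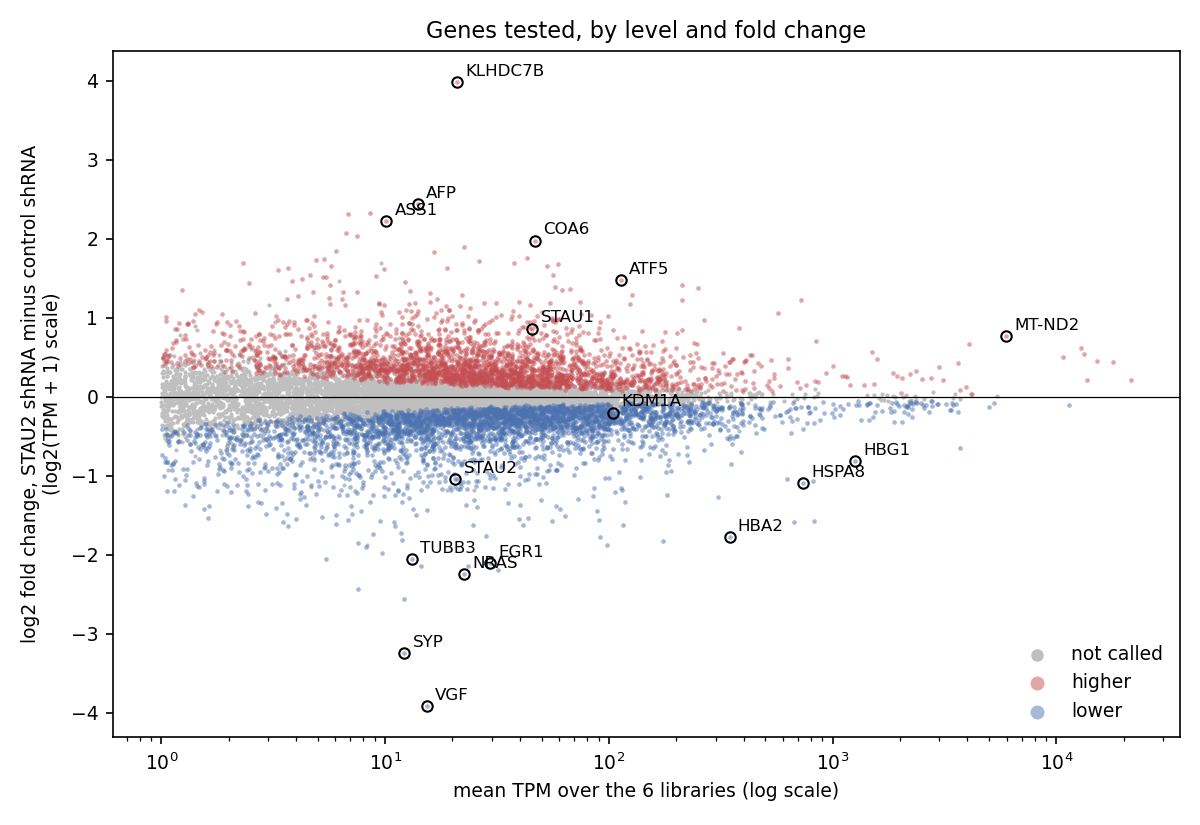
Log2 fold change (vertical axis, STAU2 shRNA minus control shRNA) against the mean TPM over the 6 libraries (horizontal log axis), 1 point per tested gene, with higher genes in red, lower genes in blue and others in grey. The 6081 called genes lie on both sides of 0, with KLHDC7B (3.98) and VGF (-3.92) at the extremes among the circled genes.

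Of the 27 lists tested, 13 passed camera with the preset correlation, 22 passed fry, and 0 passed camera with an estimated correlation, where 7 had an unadjusted p under 0.05. Among the genes named from the other lists, a lower-linked word also stands in the 3′ UTRs of RBM8A, BAG1, ITGA2B, KDM7A, CCNE2, ZMAT3, ALDH1L2, TRIB3, SEL1L, SEC61B, DNAJB4, NDUFA10, RPS15, HIST1H2AG and SYNCRIP, a higher-linked word in those of SMG9, XBP1, KMT2C, SESN1, BAK1, ADAR, HIST1H2AC and IGF2BP3, and words of both kinds in those of XK, RAB27B, MSI2, G2E3, MCL1 and WDR12. These genes include some that rose and some that fell with words of either kind. Of the 183 tested genes with an annotated 3′ UTR and a called fall of at least 2-fold, 40.4% hold a lower-linked word. Of those without such a fall 21.8% hold one. Of the 105 with a called rise of that size 40% hold a higher-linked word, against 13.5% of those without such a rise. The words were picked from the same fold changes, so these shares are not an independent test. All 13 tested transcripts of the mitochondrial genome, of 15 listed, rose (13 adjusted over the list alone), with a median log2 fold change of 0.44 (camera adjusted p = 9.91e-09; adjusted p = 0.255 with an estimated correlation). MT-ND2 went from 4393 ± 138 to 7465 ± 258 TPM and MT-CYB from 3137 ± 100 to 4973 ± 131 TPM. Mitochondrial transcripts took 12.2% ± 0.370 of all TPM in the control libraries and 16.2% ± 0.476 in the STAU2 shRNA libraries (SD, n = 3 each). Nuclear genes of oxidative phosphorylation moved the other way: 4 of 54 rose and 37 fell (4 and 37 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 3.51e-05; adjusted p = 0.107 with an estimated correlation). NDUFB5 (-1.16) and NDUFB8 (-0.80), both with lower-linked words, fell most, while NDUFA10 (0.53) and SDHB (0.48) rose.

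Replication-dependent histone genes had the lowest median of the lists. Of 33 tested, 25 fell and 1 rose (26 and 1 adjusted over the list alone), with a median of -0.95 (camera adjusted p = 4.43e-08; adjusted p = 0.107 with an estimated correlation). HIST1H1E, a linker histone gene, fell from 12.4 ± 0.771 to 2.77 ± 0.660 TPM and HIST1H2AG from 44.1 ± 0.806 to 12.3 ± 0.311 TPM, while HIST1H2AC rose (0.31). Histone genes are near-identical copies, so the split of reads between them is uncertain. Genes of the G1/S transition leaned lower, with 25 of 51 lower and 7 higher (25 and 8 adjusted over the list alone) and a median of -0.13 (camera adjusted p = 0.0291; adjusted p = 0.151 with an estimated correlation). CCNE2, a cyclin gene of S phase entry (-1.24), and RRM2, a subunit of ribonucleotide reductase (-0.67), fell, and the helicase subunit gene MCM6 (0.58) and PRIM1 (0.30) rose. The G1/S call was lost without mitochondrial genes (median -0.083, adjusted p = 0.0518), whose share of TPM differed between the groups, and without genes that hold a word (median -0.092, adjusted p = 0.214). Of 56 G2/M genes 21 rose and 15 fell (21 and 17 adjusted over the list alone; camera adjusted p = 0.403), with NDC80 (0.50) and TMPO (0.47) higher and G2E3 (-0.87) and TUBB4B (-0.48) lower.

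Nucleolar and ribosome assembly genes known as MYC targets fell together, with 32 of 42 lower and 2 higher (32 and 3 adjusted over the list alone) and a median of -0.35 (camera adjusted p = 7.13e-08; adjusted p = 0.107 with an estimated correlation). SRM, the spermidine synthase gene, went from 235.9 ± 5.0 to 135.4 ± 2.10 TPM and RRP9 from 34.7 ± 1.08 to 19.7 ± 0.409 TPM, while LYAR (0.49) and WDR12 (0.12; adjusted p = 0.0641 without control replicate 2 and 0.0507 without STAU2 shRNA replicate 3, and 0.0569 without the trend) rose. MYC itself stood at 159.9 ± 2.5 and 152.7 ± 0.945 TPM (limma adjusted p = 0.0640). Ribosomal protein genes shifted slightly, with 47 of 77 lower and 9 higher (50 and 9 adjusted over the list alone) and a median of -0.08 (camera adjusted p = 0.00182; adjusted p = 0.489 with an estimated correlation). RPS26 (-0.53) and RPS15 (-0.32) fell and RPL27 (0.48) and RPL7 (0.29) rose. This list's call was lost without mitochondrial genes (median -0.031, adjusted p = 0.309), whose share of TPM was higher in STAU2 shRNA.

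**Figure D3:**
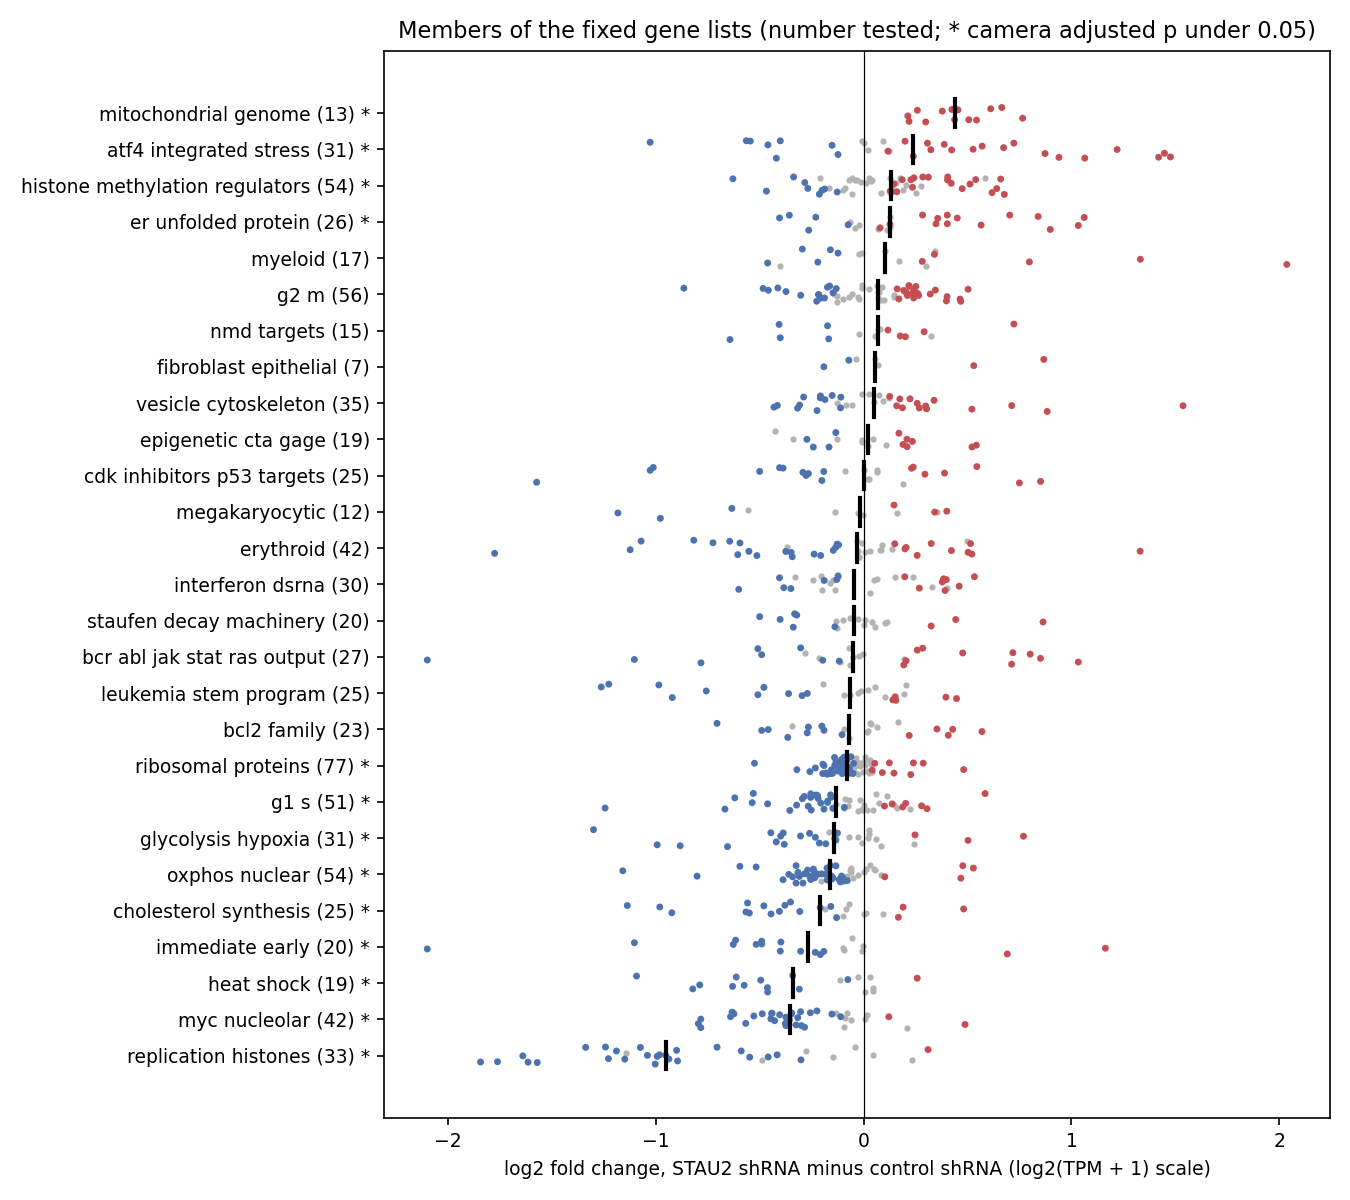
Log2 fold change (horizontal axis, STAU2 shRNA minus control shRNA) of the tested members of the 27 lists (vertical axis, number tested in brackets), with called higher members in red, called lower members in blue, others in grey and the median as a black bar. Asterisks mark the 13 lists past camera with the preset correlation, from the replication histones (median -0.95) to the mitochondrial genome (0.44).

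Targets of ATF4, the transcription factor of the integrated stress response, leaned higher, with 18 of 31 higher and 8 lower (19 and 8 adjusted over the list alone) and a median of 0.24 (camera adjusted p = 0.000576; adjusted p = 0.225 with an estimated correlation). ATF5 rose from 59.2 ± 2.76 to 166.5 ± 8.25 TPM and ALDH1L2, a mitochondrial folate enzyme gene, by a log2 fold change of 1.45, while GDF15 (-1.03) and TRIB3 (-0.57), also on this list, fell. Unfolded protein response genes of the endoplasmic reticulum leaned higher too, with 14 of 26 higher and 5 lower (14 and 6 adjusted over the list alone; median 0.13; camera adjusted p = 0.00693; adjusted p = 0.151 with an estimated correlation). SEL1L (1.06) and XBP1 (1.03), a transcription factor gene of this response, rose, and SDF2L1 (-0.41) and SEC61B (-0.36) fell. Without genes that hold a word, which leaves fewer members, the median was 0.11 and the call was lost (adjusted p = 0.169). Heat shock genes fell, with 12 of 19 lower and 1 higher (13 and 1 adjusted over the list alone; median -0.34; camera adjusted p = 0.00182; adjusted p = 0.107 with an estimated correlation). HSPA8, a constitutive chaperone gene, went from 1006 ± 5.38 to 470.9 ± 10.1 TPM, and its 3′ UTR holds GACCTAA. DNAJB4 fell (-0.82) and HSP90AB1 rose (0.26).

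Most immediate early genes were lower. Among immediate early genes 13 of 20 fell and 2 rose (13 and 2 adjusted over the list alone; median -0.27; camera adjusted p = 0.00693; adjusted p = 0.255 with an estimated correlation), led by EGR1 and FOS (-1.10). BTG1 (1.16) and KLF6 (0.69), both with GAAGATC in the 3′ UTR, rose. The list of BCR-ABL, JAK-STAT and RAS output genes did not pass (10 of 27 higher and 8 lower; 11 and 10 adjusted over the list alone; camera adjusted p = 0.514); its camera direction was up and its median (-0.05) and mean (-0.03) were below 0. PIM2, a survival kinase gene, rose from 151.8 ± 2.47 to 274.6 ± 5.64 TPM.

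Cholesterol synthesis genes leaned lower, with 15 of 25 lower and 3 higher (16 and 3 adjusted over the list alone; median -0.21; camera adjusted p = 0.00182; adjusted p = 0.107 with an estimated correlation). PMVK (-1.14) and ACAT2 (-0.98), both with CTAATAA, fell. Without genes that hold a word, which leaves fewer members, the median was -0.20 and the adjusted p 0.0542. Glycolysis and hypoxia genes fell in 17 of 31 cases and rose in 3 (17 and 3 adjusted over the list alone; median -0.15; camera adjusted p = 0.00812; adjusted p = 0.245 with an estimated correlation), with PFKP (-1.30) and ENO2 (-0.99) lower and PDK1 (0.77) and BNIP3L (0.50) higher. The 3′ UTRs of these 4 genes hold lower-linked words, and that of PDK1 also holds the higher-linked GAAGATC.

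Regulators of histone methylation leaned higher, with 20 of 54 higher and 9 lower (21 and 10 adjusted over the list alone; median 0.13; camera adjusted p = 0.0453; adjusted p = 0.245 with an estimated correlation). KMT2C (0.68) and KDM7A (0.66) rose, and PRMT5, an arginine methyltransferase gene (-0.63), and KDM1B (-0.47) fell. KDM1A, which encodes the lysine demethylase LSD1, fell by 0.20 on the log2 scale (SE 0.0326, adjusted p = 0.000993), from 111.6 ± 2.62 to 97.0 ± 2.16 TPM. The list's call was lost without control replicate 3 (median 0.11, adjusted p = 0.0614), STAU2 shRNA replicate 2 (0.12, adjusted p = 0.0632) or STAU2 shRNA replicate 3 (0.14, adjusted p = 0.0517). It was also lost under quantile normalization (median 0.15, adjusted p = 0.0537) and with a mean of at least 5 TPM (0.13, adjusted p = 0.103). Without genes that hold a word the median was lower (0.063, adjusted p = 0.214).

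Globin transcripts were lower. HBA2 went from 536.1 ± 24.1 to 155.8 ± 8.60 TPM and HBG1, a fetal globin gene, from 1613 ± 26.9 to 914.3 ± 14.0 TPM. HBA1 with HBA2, which share reads, fell to 41.5% of the control level when summed, and HBG1 with HBG2 to 62.0%. Of the 8 globin genes tested, a subset chosen after the values were seen, 7 fell and none rose, with a median of -0.69. The erythroid list as a whole did not pass, with 10 of 42 higher and 19 lower (10 and 19 adjusted over the list alone; camera adjusted p = 0.272). HEMGN fell (-1.12) and XK (1.33) and the heme synthesis gene PPOX (0.52) rose. GATA1, the erythroid master regulator, stood at 227.5 ± 4.88 and 223.7 ± 3.33 TPM (adjusted p = 0.474).

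Other blood lineage and leukaemia programs went both ways. Of 12 megakaryocytic genes 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.929), with ITGA2B (-0.98) and RAB27B (-1.18) lower and RUNX1 (0.34) and PLEK (0.40) higher. Of 17 myeloid genes 5 rose and 5 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.403), with CSTA and the Fc receptor gene FCGR1A (1.33) higher and CD68 (-0.46) and ITGAX (-0.30) lower. Leukaemia stem cell genes split into 5 of 25 higher and 10 lower (6 and 10 adjusted over the list alone; camera adjusted p = 0.403), with CD44 (-1.26) and PBX3 (-1.23) lower and MECOM (0.45) and MSI2 (0.40) higher. The calls of PLEK and ITGAX were lost without single libraries: for PLEK, the adjusted p was 0.0916, 0.134 and 0.0728 without control replicates 1, 2 and 3 and 0.132 without STAU2 shRNA replicate 2 (log2 fold change 0.26), and for ITGAX 0.0700 and 0.0859 without control replicates 1 and 3 and 0.0508 and 0.0693 without STAU2 shRNA replicates 1 and 3. The call of PLEK was also lost with no filter (adjusted p = 0.0800), with a pseudocount of 5 TPM (log2 fold change 0.18, adjusted p = 0.0501) and without genes that hold a word (0.0504).

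Lists of cell death and arrest genes did not pass camera. Among CDK inhibitors and p53 targets 7 of 25 rose and 11 fell (7 and 11 adjusted over the list alone; camera adjusted p = 0.674, direction down, with a median of 0.0026 and a mean of -0.10), while fry, which does not compare a list with other genes, gave an adjusted p of 0.000899 (down). CDKN1A, which encodes the cell cycle inhibitor p21, fell from 14.7 ± 0.551 to 4.25 ± 0.168 TPM and GDF15 fell as above, while ZMAT3 (0.85) and SESN1 (0.75) rose. In the BCL2 family 5 of 23 rose and 9 fell (5 and 10 adjusted over the list alone; camera adjusted p = 0.538). BAK1, a pro-death member (0.57), and BCL2 (0.43) rose, and BOK (-0.71) and the pro-survival gene MCL1 (-0.49) fell. BCL2 had under 2 TPM in each group, and its adjusted p was 0.0518, 0.0666 and 0.05004 without control replicates 1, 2 and 3.

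In the interferon and double-stranded RNA response list, 8 of 30 rose and 7 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.748, direction up, with a median of -0.05 and a mean of 0.02). ADAR, an RNA editing enzyme gene (0.53), rose and IFI6 (-0.60) and BST2 (-0.41) fell. Staufen and nonsense-mediated decay factors did not pass, with 3 of 20 higher and 6 lower (3 and 6 adjusted over the list alone; camera adjusted p = 0.519). STAU1 and NBAS (0.44) rose, SMG9 (-0.50) and RBM8A (-0.40) fell, and the decay helicase gene UPF1 stood at 53.5 ± 0.869 and 53.5 ± 1.48 TPM (adjusted p = 0.995). Known targets of nonsense-mediated decay also went both ways, with 5 of 15 higher and 5 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.514), BAG1 (0.72) and CARS (0.29) being higher and GADD45A (-0.64) and HNRNPDL (-0.41) lower.

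Of 35 vesicle and cytoskeleton genes 14 rose and 12 fell (15 and 12 adjusted over the list alone; camera adjusted p = 0.519). The RNA-binding protein genes SYNCRIP (1.54) and IGF2BP3 (0.88) rose and TUBA1A (-0.43) and KIF5A (-0.42) fell. Among cancer-testis genes 7 of 19 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.403). MAGEA1 (0.54) and MAGEA4 (0.52) rose, and CTAG2 (-0.27) and MAGEA6 (-0.24) fell, with near-identical copies making the split of reads uncertain. The adjusted p of MAGEA4 was 0.0530 without control replicate 1, and that of CTAG2 lay between 0.0566 and 0.136 in the 5 leave-one-out fits that lost its call, all but the one without STAU2 shRNA replicate 1 (log2 fold change -0.18 without STAU2 shRNA replicate 3). The call of CTAG2 was also lost under quantile normalization (adjusted p = 0.0524), TMM scaling (0.0609), without mitochondrial genes (0.0845), with no filter (0.0934) and with no trend (0.0679).

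Markers of other cell types were few. Of T and NK cell markers 3 of 21 were tested and all 3 fell (3 adjusted over the list alone), among them CD3D (-0.97) and PRF1 (-0.64). Of B cell markers 2 were tested, of which 1 fell (1 adjusted over the list alone). Of 7 fibroblast and epithelial markers 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.514). FN1 went from 45.1 ± 1.40 to 83.1 ± 2.61 TPM and COL1A2 rose by 0.53, VIM, abundant in these cells, fell slightly (-0.19), and KRT8 lay near the threshold (-0.07, adjusted p = 0.0491). The adjusted p of KRT8 lay between 0.0671 and 0.152 in the 5 leave-one-out fits that lost its call, all but the one without STAU2 shRNA replicate 1. Scaling moved its log2 fold change to -0.024 under quantile normalization (adjusted p = 0.445), -0.044 under TMM scaling (0.194) and -0.021 without mitochondrial genes (0.477), and the call was also lost with no filter (0.0604), no trend (0.176) and array weights (0.0516).

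The authors' own calls followed the same directions. Of the genes called in the authors' deposited table with 1 row per symbol, 5254 were tested here. Of these, 5096 were called by limma in the same direction and 0 in the opposite one. Symbols with several rows were left out of this comparison. For 2186 higher and 2910 lower genes shared with the authors' deposited table, independent lists would share 509 and 867. Both rest on the same libraries. STAU2 had an effect of -0.761 on the natural log scale in the authors' deposited table (q = 7.64e-18) and EGR1 -1.52. The estimated variance between libraries was at or below 0 for 52.9% of the rows of the authors' deposited table.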

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

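The effect of scaling on STAU1, the G1/S test on histones, the place of the joined sequence in STAU2 and the counts without genes that hold a word were tested only after the results were seen.

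Some noncoding genes appear in the authors' deposited table without a row in the TPM table, which holds few of them. Of the calls of the authors' deposited table with no row in the TPM table, 289 were higher in STAU2 shRNA and 381 lower. In the authors' deposited table SNHG16 was 1.61-fold higher, STAG3L5P-PVRIG2P-PILRB 1.72-fold, CCDC183-AS1 2.35-fold, TDRG1 3.00-fold and the imprinted gene H19 1.66-fold. The libraries' own values for these genes were not analysed here.

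The 6 libraries make 10 splits, too few for a share under 0.05. The real split gave 6081 genes (2656 higher and 3425 lower) and the highest other 0 in each count, and 1 of 10 splits reached each real count. For the lists, the real split gave 13 and the highest other 6, again with 1 of 10 splits as large. Each other split mixes both groups, which puts the group difference into the spread within each side. The low gene counts of the other splits were therefore largely fixed in advance and do not argue against chance.

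Some of the large falls and rises may come from the hairpins themselves. Genes holding CCTAATA in the 3′ UTR had the lowest score of all words (-13.75, family-wise permutation p = 0.001, the smallest that 1000 permutations can give). Their median log2 fold change was -0.11, against -0.025 for genes without the word. The 4 overlapping words join to GACCTAATAA, which stands in the coding sequence of 13 of 29 annotated STAU2 transcripts (chromosome 8, 73595254 to 73595263, minus strand, GRCh38). A seed of the STAU2 hairpin is therefore a candidate source. Chance with equal base use would place a given sequence of that length there in 0.853% of cases. This sequence was put together after the scores were seen, so that share is not a test. The next lowest word, GCCTAAT (score -7.00, family-wise permutation p = 0.001), stands in 0 of 29 STAU2 transcripts. Single 7-base words from the other side stand there too, such as AAGATCT (score 5.35) in 14 of 29. GAAGATC had the highest score (12.84, permutation p = 0.001, likewise the smallest), as silencing of these genes by the control hairpin would give. GAAGATC also stands in the 3′ UTR of 4 of 29 STAU2 transcripts. STAU2 was the target of the STAU2 shRNA, so its fall cannot decide on the control hairpin. Among the genes in which none of these words was found, 117 still fell and 53 rose at least 2-fold. They include genes with no annotated 3′ UTR, which could not be searched, and only 1 transcript per gene was searched. The hairpin sequences were not used here, and an effect of lower STAU2 on the same genes stays open.

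The rise of STAU1 may reflect compensation for STAU2 or release from the control hairpin. Reads shared by both genes are argued against, since 0% of 4311 distinct 31-base words of STAU1 transcripts occur in STAU2 transcripts. Scaling is argued against too, with a log2 fold change of at least 0.883 under quantile and TMM scaling. In favour of release, GAAGATC stands in 3 of 8 annotated STAU1 3′ UTRs (chromosome 20, 49113388 to 49113394, minus strand, GRCh38) and AAGATCA in all 8. The median log2 fold change was 0.16 for the 717 genes with GAAGATC and 0.092 for the 1193 with AAGATCA, against 0.86 for STAU1. A word thus went with a far smaller median rise than that of STAU1, so its presence is weak support. A median over many genes cannot decide for a single gene. A biological response to STAU2 was not tested apart from release.

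Replication histone transcripts, which lack a poly(A) tail, may be lower through capture of such RNAs, if RNA was selected by that tail, or through fewer cells in S phase. Only 2 small structured RNAs were called in either table, 1 of them lower, too few to decide on capture. The G1/S list's median lay at percentile 3.06 of 10000 random lists of the same size and level, just inside the lower bound set for it. Camera with the preset correlation, which compares the list with all other tested genes, put it lower (adjusted p = 0.0291). That call was lost with an estimated correlation (camera adjusted p = 0.151), without mitochondrial genes (0.0518) and without genes that hold a word (0.214). Fewer cells in S phase are thus neither shown nor excluded. An effect of STAU2 on histone transcripts stays open.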

How the results depend on the processing

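Depth is unknown for TPM. STAU2 kept its direction and call in its 17 alternatives (log2 fold change -1.14 to -0.86), and leaving out single libraries moved the called genes to between 5230 and 5718, those higher to between 2320 and 2487, those lower to between 2899 and 3232 and the lists to between 12 and 13. With a minimum of 2-fold, 302 genes remained by construction (108 higher and 194 lower). Lists past the threshold numbered 0 with an estimated correlation and 22 with fry, which does not compare a list with other genes. Replicate numbers did not pair the libraries (deviations of same-numbered libraries correlated at 0.019, 0.011 and -0.014), and a replicate block gave 5864 called genes, 5685 of them shared with the unblocked fit, losing the calls of PLEK, ITGAX, CTAG2 and KRT8 among named genes. Of calls, 49.5% were higher after quantile normalization, 49.0% after TMM scaling and 53.03% without mitochondrial genes, against 43.7%; this last setting and the one without genes that hold a word were chosen after seeing the data.

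The adjusted p under 0.01 and the minimum of 2-fold were applied to the counts of genes only, not to named genes. Of 123 called named genes, 115 kept direction and call in each other alternative with a value. The rest included PLEK, ITGAX, BCL2, WDR12, MAGEA4, CTAG2 and KRT8. GATA1 and UPF1, near 0, changed sign; for these and the lists that follow the cause was not tested. GATA1 was at 0.039 under quantile normalization, 0.0031 under TMM scaling and 0.026 without mitochondrial genes, and UPF1 at -0.00475 with array weights and between -0.021 (without STAU2 shRNA replicate 2) and 0.016 with single libraries left out. Lists that did not pass turned in camera direction. With a mean of at least 5 TPM the leukaemia stem list's median was 0.038 and the interferon list's, already below 0, was -0.13 with the direction now down. The megakaryocytic median ran from -0.050 without control replicate 1 to 0.056 without control replicate 2, and was 0.15 without genes that hold a word, where the vesicle and cytoskeleton median was -0.071.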

Other observations

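The 8 gene lists below were chosen and tested after the data were seen, so that no p-value is given for them. Of 31 proteasome subunit genes 23 were lower and 1 higher, with a median log2 fold change of -0.23. PSMA2 went from 174.1 ± 0.872 to 56.1 ± 5.34 TPM and PSMB2 from 170.0 ± 2.13 to 113.0 ± 3.61 TPM, both with lower-linked words in the 3′ UTR, while PSMC3 rose (0.18). Transcripts of nuclear genes for mitochondrial ribosomal proteins fell in 44 of 70 cases and rose in 5 (median -0.20), while all 13 tested transcripts of the mitochondrial genome rose. MRPS14 (-0.75) and MRPS25 (-0.73) fell and MRPL12 rose (0.61). The 3′ UTR of MRPS25 holds a lower-linked word, as do those of LMAN1, TMED7 and GORASP2, while SYN1 and ICAM1 hold a higher-linked one and TF, GOLGA2 and RAB3B hold both kinds. Both medians stayed below 0 under quantile normalization (-0.18 and -0.16), under TMM scaling (-0.21 and -0.18) and without mitochondrial genes (-0.18 and -0.15), and without genes that hold a word (-0.19 and -0.20).

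Genes of coated vesicles and the Golgi leaned higher, with 17 of 35 higher and 4 lower (median 0.11), among them GOLGA2 (0.52), LMAN1 (0.45) and TMED7 (0.63), with GORASP2 lower (-0.42). NRF2 targets of the oxidative stress response fell in 16 of 27 cases and rose in 3 (median -0.19). TALDO1, a pentose phosphate pathway gene whose 3′ UTR holds CCTAATA, went from 433.1 ± 3.97 to 178.6 ± 4.76 TPM. Neuronal vesicle genes that fell besides VGF, SYP and TUBB3 included STMN3 (-1.57), CPLX1 (-1.54) and SYN1 (-1.04), while NSG1 (1.73, with overlapping groups), RAB3B (0.59) and BEX2 (0.31) rose, in a list with 8 of 17 lower and 3 higher. Of 8 genes of liver-secreted proteins and their regulation 4 rose, among them AFP, the transferrin gene TF (1.65), MLXIPL (1.63) and the antithrombin gene SERPINC1 (1.10). NF-κB targets split into 6 higher, led by ICAM1 (1.69), and 6 lower of 17, among them CXCL8 (-0.81) and RELB (-0.70). Mean levels were under 3 TPM in both groups for SYN1, CPLX1, RAB3B, SERPINC1 and CXCL8, and in the control libraries for NSG1 and TF. The folds of these genes depend on the pseudocount. Of 35 lysosome genes 11 rose, PSAP (0.48) most, and 7 fell.

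In the authors' deposited table, noncoding genes with no TPM row that were lower in STAU2 shRNA included NEAT1 (1.58-fold), DANCR (1.83-fold), FGD5-AS1 (1.93-fold), DLGAP1-AS2 (1.61-fold) and SNHG4 (1.88-fold).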
